A study of Mus musculus with 9 samples.

How the data were processed

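The series holds RNA sequencing of melanocytes, the pigment-producing cells of skin, sorted by flow cytometry from mouse epidermis. Per the labels' protocols, RNA was extracted with Trizol, libraries were made with a SMART-Seq v4 kit for small amounts of RNA, and sequencing was paired-end on an Illumina NovaSeq instrument. There were 3 groups of 3 libraries. Control tail libraries came from mice with both copies of Spry1 floxed. Knockout tail and knockout back libraries came from floxed mice that also carry a Cre recombinase fused to an oestrogen receptor domain under the keratin 14 promoter. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

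The deposited file is 1 table of 16299 genes by 9 columns on a log2 scale, with values from 5.85 to 20.9. The submitters' processing notes name DESeq2 and the mouse build GRCm38, with no version or role. The aligner, the counting program and the strand setting are not given in the sources used here. The form of the deposited values was worked out from the values themselves. They followed the variance-stabilising curve that DESeq2, named in the submitters' processing notes, can produce: a gene at 0 counts has a value of 7.98, and large values approach log2 of a normalised count. A log2 difference on this curve understates the change of a gene with few counts.

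In every gene the mean of the third knockout tail and the third knockout back libraries equalled the mean of the other 7 libraries, to within 7.14e-09. The next best of the 255 ways to part the libraries differed by up to 1.50. A shift between those 2 sets of libraries had therefore been removed before deposit, with no allowance for group. All 3 control libraries lay in the larger set. The shift that had been removed had a median absolute size of 0.45 on the log2 scale and exceeded 1 in 18.2% of genes. Because the smaller set held knockout libraries and no control, this step took some of the knockout difference out of the deposited values.

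Undoing the curve and the shift gave whole counts for 16296 genes, each within 0.004 of a whole number, which was also the tolerance set. The other 3 genes, Dct, Pmel and Tyrp1, had counts too high to resolve. On simulated data the recovery returned 1500 of 1500 genes exactly. The sets, the curve and the size factors were given to it there, so how these were found was not tested. Recovered totals ran from 45.7 to 67.9 M per library. Normalised counts below are recovered counts divided by the size factor of the library, and they do not contain the shift removal. Intervals for counting error are not given, since counting error is small beside the spread between libraries at these totals.

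Gene symbols were matched to GENCODE vM21 on GRCm38 for 15905 genes and to RefSeq names for 305 genes, and 89 were kept as deposited. Coordinates are from that annotation, counted from 1.

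The main test was limma (version 3.58.1, R 4.3.3) with mean-variance trend and robust moderation on the deposited values of all 9 libraries, with group as the only term. Adjusted p-values are Benjamini-Hochberg, with a threshold of 0.05. The test had been fixed for normalised values with log2 of the value plus a pseudocount. The values were already on a log scale, so no pseudocount was added, and the fixed filter on low values removed no gene. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over all lists and comparisons, for lists with at least 5 members in the table. Each list was also tested with an estimated correlation, with fry, and with camera in up to 16 other settings, fewer where a filter left under 5 members, and in 9 fits that each leave out 1 library. The text gives how many of the camera settings passed the threshold in the same direction. Camera used neither array weights nor the choice of trend and robust moderation. The settings without trend or robust moderation, and with array weights, therefore repeat the main camera test. Array weights with the library set as a term repeat the setting with that term alone. Passes in these repeats are included in the numbers given but are no further support. Lists, groups, tests and alternatives were fixed before the data were examined. A fit with the library set as a second term was added after seeing the data. It gives the difference within sets, and its estimates do not change when the removed shift is put back, so its result is given where it ends a call that the text reports.

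On simulated data with the spread and set shift of these libraries, the group-only fit of knockout tail versus control tail recovered 0% of genes changed by 1 and 0% of genes changed by 2 on the log2 scale, among 16296 genes. The fit with the set term recovered 3% and 21%. For knockout back versus knockout tail the group-only fit recovered 6.4% and 37.8%, and the set-term fit 4% and 31%. Over 5 draws, each with changes of both sizes, 37 of the 258 calls of that group-only fit were false, 14.3%, more than the 5% aimed for. With the set term 11 of 186 were false, 5.91%, and for knockout tail versus control tail 2 of 122.

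Genes are named by a fixed rule. It takes Spry1 in every comparison, and the 6 genes with the largest positive and the 6 with the largest negative difference among called genes whose groups do not overlap. Their mean must be at least 5 in the higher group, which every gene on this scale meets. Predicted models, unnamed genes, mitochondrial genes and ribosomal protein genes are excluded from that part. The rule adds up to 4 called members per gene list, or where none was called the member with the highest mean, by value only. It adds the level of Tyr, Dct, Pmel, Mitf, Kit, Sox10, Krt14 and Krt5. Genes outside this rule were chosen after their values were seen. The levels of single genes and of marker lists were also compared by exact two-sided permutation tests, for which 3 libraries against 3 cannot give a p below 0.1. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.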

Results

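Melanocytes were profiled from the tail epidermis of control mice. The knockout groups came from the tail and the back epidermis of mice with a keratin 14 driven Cre, meant to delete floxed Spry1. The values do not show whether it was deleted. Spry1 encodes an inhibitor of receptor tyrosine kinase signalling. Keratin 14 is made by basal keratinocytes, so the deletion is aimed at the cells that surround the sorted melanocytes. There were 3 libraries per group. Recovered totals were 66.3 to 67.9 M (mega) counts in control tail, 45.7 to 65.6 M in knockout tail and 47.7 to 57.1 M in knockout back.

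Melanocyte genes were among the highest in the table. The deposited level of Pmel, a structural protein of melanosomes, was 20.19 in control tail, 20.93 in knockout tail and 19.99 in knockout back. Dct, an enzyme of melanin synthesis, lay at 20.14, 20.40 and 20.46, and Tyr at 17.93, 18.08 and 17.52. Keratinocyte transcripts were present as well. The normalised count of Krt14 was 46890 ± 22438 in control tail, 69476 ± 90421 in knockout tail and 59254 ± 27435 in knockout back (mean ± SD, n = 3). The knockout tail mean rests on the third library, with 173342 against 26753 and 8333 in the others. In the deposited values, from which the set shift was removed, Krt14 was lower in knockout tail (15.40) than in control tail (16.35), and neither order passed a test.

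The libraries were not alike in quality. The first and second knockout back libraries had 4628 and 6127 genes at 0 counts, against 854 to 1739 in the other 7. Their totals, 52.8 and 47.7 M, were above the 45.7 M of the third knockout tail library, which had the 854. Over the 500 most variable genes the first principal component held 64.2% of the variance and placed those back libraries at 34.1 and 61.6, with the other 7 between -22 and 5.36.

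Libraries also differed in sex-linked transcripts, which were examined after the values were seen. The Y-linked gene Ddx3y had 0 counts in all 3 control libraries and in the third knockout tail library, and 1393 and 2266 in the first and second knockout tail libraries. It had 1177, 137 and 2302 in the back libraries, which also had 1313, 1266 and 2699 counts of Xist, the transcript of the inactive X. The first and second knockout tail libraries had 5 and 19 counts of Xist. Another Y-linked gene, Eif2s3y, had 154, 0 and 9 counts in control tail, 4890, 5677 and 0 in knockout tail and 3275, 2543 and 3922 in back. At least 2543 counts of Eif2s3y were therefore found in 5 of 6 knockout libraries and in no control, so sex is largely tied to genotype.

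**Figure D1:**
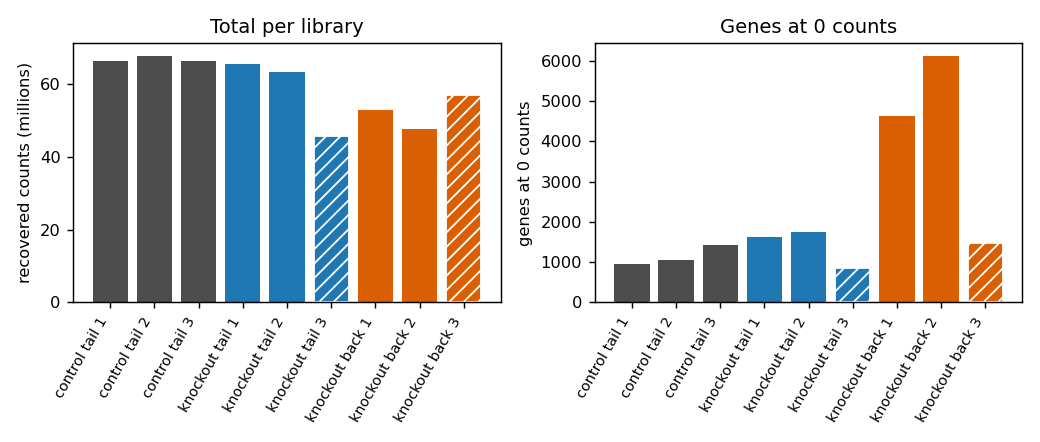
Recovered counts per library in M (left) and genes at 0 counts (right), 1 bar per library, coloured by group; hatched bars are the third knockout tail and the third knockout back libraries, which form the smaller set. The first and second knockout back libraries have 4628 and 6127 genes at 0, and the other 7 have 854 to 1739.

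Spry1 itself (chromosome 3, 37639947 to 37644598, plus strand, GRCm38, protein coding, ENSMUSG00000037211.12) had recovered counts of 1915, 1298 and 1587 in control tail, 4446, 2082 and 508 in knockout tail and 2120, 0 and 761 in knockout back. The deposited level was 10.48 ± 0.18 in control tail, 10.95 ± 0.71 in knockout tail and 9.78 ± 1.84 in knockout back (SD, n = 3). None of the differences exceeded the spread: the exact two-sided permutation p was 0.5 for knockout tail against control tail, 0.5 for back against tail and 0.9 for back against control, where 0.1 is the smallest possible. The value is of little use as a check of the labels, since the sorted cells are not those in which the promoter drives Cre, and the position of the floxed part within the gene is not given in the labels.

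The first comparison, knockout tail against control tail, asks how melanocytes differ at one body site when Spry1 deletion is aimed at the surrounding epidermis. Among the gene lists tested by camera, the clearest difference was in interferon-induced genes. All 24 measured members of the interferon response list had a higher mean in knockout tail, with a median difference of 1.37 on the log2 scale. Ifit3, an interferon-induced antiviral protein (chromosome 19, 34583531 to 34588731), had a normalised count of 39530 ± 13952 in knockout tail against 3006 ± 468 in control tail. Usp18, which removes the ubiquitin-like ISG15 from proteins, had 4996 ± 991 against 251 ± 113. Both values are mean ± SD with n = 3. Each knockout tail library lay above each control library in Ifit3 and Usp18, an arrangement that chance gives in 10% of genes for 3 against 3 in either direction.

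No single gene passed in this comparison. The limma group-only fit called 0 of 16299 genes, with 814 at an unadjusted p under 0.05, and limma-voom on the recovered counts also called 0. Within the interferon list 11 genes passed when adjusted over the list alone. With the library set as a term, limma called 10 genes: Usp18, Ifit3, Oas1a, Ifit3b, Ifitm3, Selenop and Tyrp1 were higher in knockout tail, and Syt5 and the unnamed models Gm11175 and 6330408M09Rik were lower. These lower genes lay at or near 0 counts in knockout tail: 0, 0 and 0 for Syt5, 3, 0 and 0 for Gm11175 and 0, 0 and 53 for 6330408M09Rik. Ties at 0 counts narrow their spread. The difference of Ifit3 was then 3.45 with an adjusted p of 0.045, and that of Usp18 3.12 with 0.043. The difference of Tyrp1, a melanosomal enzyme, was 0.99 with an adjusted p of 0.048. Selenop, a plasma selenium carrier, differed by 1.80 with an adjusted p of 0.043. In that fit 3 interferon list members passed over all genes and 14 when adjusted over the list alone. With limma-voom and the set term the count was again 0, and in the 7 libraries of the larger set alone, where knockout tail keeps 2 libraries, it was also 0. The 10 genes thus depend on a setting added after the data were seen.

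The interferon list stood apart from other genes by camera, adjusted p = 1.9e-20. That call was lost with an estimated correlation, adjusted p = 0.19, or 0.086 with the set term. Class I antigen presentation genes differed in the same direction. A higher mean in knockout tail was found in 15 of 18, with a median difference of 0.50 and a camera adjusted p of 1.6e-05 (adjusted p = 0.32 with an estimated correlation). No member passed over all genes, and 0 passed when adjusted over the list alone, or 7 with the set term. B2m, the shared light chain of class I molecules, was at 16.89 against 15.99.

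Pigment genes were slightly higher. Of 24 melanin and melanosome genes, 22 had a higher mean in knockout tail, with a median difference of 0.42 and a camera adjusted p of 4.1e-10 (adjusted p = 0.19 with an estimated correlation). None passed over all genes and 1 passed when adjusted over the list alone. The difference of Pmel was 0.74, of Dct 0.27 and of Tyr 0.15, and none of these passed. Kit, the receptor for stem cell factor, had a normalised count of 41258 ± 11468 against 16667 ± 4852 (SD, n = 3), a difference of 0.94 that did not pass (limma adjusted p = 0.70). Mitf, the main transcription factor of the lineage, differed by 0.15 and Sox10 by 0.21, neither past the threshold. The list of lineage regulators did not pass camera (adjusted p = 0.24), nor did the list of targets and feedback genes of the ERK pathway, in which 9 of 21 members had a positive difference (adjusted p = 0.23).

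Ribosomal protein genes and mitochondrially encoded genes lay lower in knockout tail by camera. Of 86 ribosomal protein genes 3 had a positive difference, with a median of -0.32 and an adjusted p of 1.8e-14 (adjusted p = 0.31 with an estimated correlation). Of the 13 mitochondrially encoded genes 0 did, with a median of -0.50 and an adjusted p of 3.9e-07 (adjusted p = 0.31 with an estimated correlation). Immediate early and stress genes had a median of -0.53 and an adjusted p of 7.9e-08 (adjusted p = 0.29 with an estimated correlation). In limma-voom on recovered counts the camera adjusted p of that list was 0.74. None of the members of these 3 lists passed over all genes, and 0 in each passed when adjusted over the list alone.

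Some lists of other cells also differed in mean. The list of muscle, fat and blood genes had a median difference of 2.73 (camera adjusted p = 0.0014, 0.29 with an estimated correlation), and 0 of its 7 members passed. The normalised count of the haemoglobin gene Hba-a1 was 37988 and 42771 in the first and second knockout tail libraries, 856 in the third, and 225 to 3455 in control tail. In the deposited values, from which the set shift was removed, the Langerhans and myeloid list differed by a mean of 0.11. The basal keratinocyte list differed by -0.44 and the differentiated keratinocyte list by -0.56. Exact permutation p of these lists were 0.2, 0.4 and 0.5 over 3 against 3 libraries. The normalised count of Krt5 was highest in the smaller set, 48852 in the third knockout tail and 31872 in the third back library. The other knockout tail libraries had 3217 and 1252, the other back libraries 10783 and 3366, and control tail 5543 to 8583. By camera the basal and differentiated lists did not pass (adjusted p of 0.14 and 0.11), but each passed as lower in 4 of 16 other settings, and in the 7 libraries of the larger set at 0.023 and 3.4e-04. Their highest camera adjusted p were 0.91 with limma-voom (basal) and 0.89 with the set shift undone (differentiated). The 2 mast cell and granulocyte genes differed by a mean of 1.011 and the 4 endothelial and pericyte genes by -0.41, each at the smallest possible exact p of 0.1 (adjusted p = 0.51).

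Further lists passed camera in knockout tail against control tail with no member past the threshold over all genes. Stem cell and neural crest genes had a median difference of 0.21 (adjusted p = 0.039, 0.31 with an estimated correlation) and lysosome and autophagy genes 0.15 (adjusted p = 0.023, 0.31 with an estimated correlation). FGF ligands and receptors had -0.37 (adjusted p = 0.045, 0.36 with an estimated correlation), anterior and central HOX genes -0.41 (adjusted p = 0.016, 0.22 with an estimated correlation) and nuclear oxidative phosphorylation genes -0.15 (adjusted p = 0.022, 0.50 with an estimated correlation). In each of these 5 lists 0 passed when adjusted over the list alone.

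Of the 14 lists past camera in this comparison, none passed with an estimated correlation, and apart from that and fry 6 passed in every other setting and every fit with 1 library left out: interferon, class I, melanin, adhesion, ribosomal and mitochondrially encoded genes. Immediate early genes passed in 14 of 16 other settings, failing with limma-voom and with the set shift undone (0.95), and the blood list in 13 of 14. Stem cell genes passed in 10 of 16, lysosome genes in 12 of 16, FGF genes in 9 of 15, HOX genes in 11 of 14 and nuclear oxidative phosphorylation genes in 12 of 16, the last at 0.084 with the set term.

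**Figure D2:**
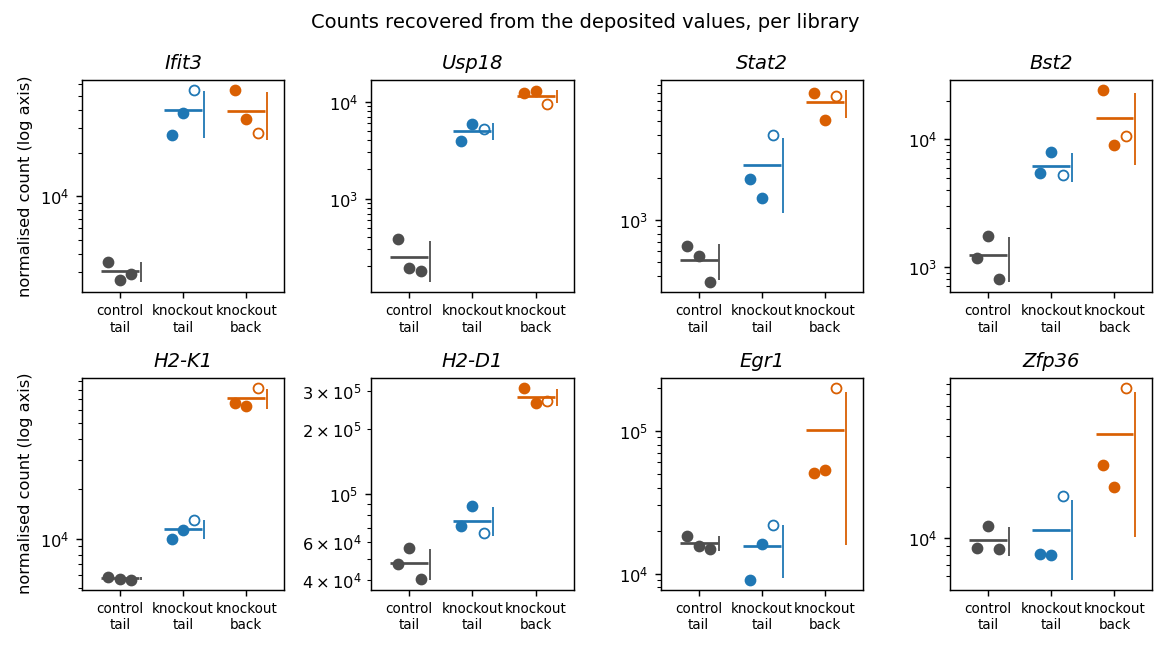
Normalised counts (log axis) of 8 genes in each library, coloured by group; horizontal lines are means, vertical lines 1 SD, and open circles the third knockout tail and the third knockout back libraries. Ifit3 lies at 39530 in knockout tail against 3006 in control tail, and H2-K1 at 70841 in knockout back against 11411 in knockout tail.

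The second comparison, knockout back against knockout tail, is of body site within one genotype. Sex-linked transcripts also differed between these groups. Eif2s3y and Xist were both counted in all 3 back libraries. The first and second tail libraries had Eif2s3y with 5 and 19 counts of Xist. The third had 0 counts of Eif2s3y and 6364 of Xist. Site was not separated from that difference. The libraries from back had higher class I antigen presentation genes and higher immediate early genes. Which cells within the sort carried these genes was not tested. Cd74, a transcript of antigen-presenting cells, had 1541, 3786 and 12775 counts in back against 132, 8 and 4443 in tail. H2-K1 (chromosome 17, 33996017 to 34000347, minus strand), a class I heavy chain, had a normalised count of 70841 ± 10070 in back against 11411 ± 1514 in tail, and H2-D1 had 281462 ± 25943 against 75541 ± 11593 (SD, n = 3). H2-K1, H2-D1, H2-Q7 and H2-Q6 rose, with log2 differences of 2.58, 1.90, 4.19 and 3.43 and adjusted p of 0.021, 0.024, 0.021 and 0.027, and each also passed with the set term. Over the list, 4 of 18 members passed over all genes and 13 when adjusted over the list alone, the median difference was 1.60, and camera gave an adjusted p of 8.2e-13 (adjusted p = 0.19 with an estimated correlation). Reads of these related genes can be shared between copies, so the split among them is uncertain.

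All 20 immediate early and dissociation stress genes had a higher mean in back, and 11 rose. The median difference was 1.47, with a camera adjusted p of 5.1e-22 (adjusted p = 0.19 with an estimated correlation), and 18 passed when adjusted over the list alone. Egr1, an early growth response factor, differed by 2.43 (adjusted p = 0.021), Zfp36, which promotes decay of inflammatory transcripts, by 1.67 (adjusted p = 0.021), Atf3 by 3.50 (adjusted p = 0.025) and Junb by 1.46 (adjusted p = 0.028). With the set term 4 members passed, and Junb did not (adjusted p = 0.053).

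Interferon list genes had a median difference of 0.85 between back and tail, with 20 of 24 positive and a camera adjusted p of 3.7e-06 (adjusted p = 0.35 with an estimated correlation). None passed over all genes and 1 passed when adjusted over the list alone. It did not pass camera in the group-only fit without the first and second back libraries, which leaves 1 back library. In the third pair, the third back against the third tail library, 21 of 24 were positive with a median of 0.64. Genes outside the list that rose included the interferon-inducible GTPases Iigp1, Tgtp1 and Ifi47, by 4.69, 3.73 and 3.57 (limma adjusted p of 0.024, 0.031 and 0.039), and each also passed with the set term.

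Of pigment genes, Mlana rose by 0.95 (adjusted p = 0.021), while Rab38 and Rab32, small GTPases of melanosome formation, fell, with differences of -1.36 and -1.22 (adjusted p of 0.031 and 0.035). With the set term Rab38 and Rab32 no longer passed (adjusted p of 0.060 and 0.063). The whole list did not pass camera (adjusted p = 0.33) but passed as lower in 2 of 16 other settings. These were quantile normalisation (0.023) and the group-only fit without the sparse back libraries, which leaves 1 back library. Of its 24 members 10 passed when adjusted over the list alone. Hoxb2, a gene of positional identity, rose by 1.96 (adjusted p = 0.022). Bcl2, an inhibitor of apoptosis, rose by 1.82 (adjusted p = 0.031). Ccnd1, a cyclin of the cell cycle entry and a target of ERK signalling, fell by 1.67 (adjusted p = 0.048). The whole list of ERK targets and feedback genes lay in the other direction, higher in back, without passing camera (adjusted p = 0.062), and its member Egr1 rose. In the third pair 10 of its 21 members were positive. Beside these, the long noncoding RNA Malat1, chosen after its values were seen, differed by 1.72 (adjusted p = 0.0057).

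The genes that fell most in back were Prl2c5, a prolactin family member, Napsa, an aspartic protease, Arfgef3, Bfsp2, an intermediate filament protein, the keratin gene Krt6b and the peptidase gene Mme. Their log2 differences were -6.06, -4.64, -4.45, -4.18, -3.55 and -3.49, with adjusted p between 0.0057 and 0.023. Prl2c5 (chromosome 13, 13182715 to 13191923) went from a normalised count of 25265 ± 10751 in tail to 42.9 ± 47.9 in back. Napsa and Bfsp2 were at 0 counts in both sparse back libraries, with 181 and 596 normalised counts in the third.

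The group-only limma fit called 244 genes, 67 higher and 177 lower in back, and in all 244 the groups did not overlap. Of the 177 lower genes 105 were at 0 counts in both sparse back libraries. With the library set as a term there were 71 calls, 23 higher and 48 lower, of which 70 were among the 244. Without the sparse first and second back libraries there were 0 calls in the group-only fit and 1 with the set term, with 1 back library left and assumed to vary like the other groups. Median centring gave 57 higher and 19 lower calls and moved the median of all genes from -0.18 to 0.35, and quantile normalisation gave 87 higher and 120 lower. The third back library minus the third tail library, the only pair within the smaller set and so without replicates, was positive for 20 of 20 immediate early genes with a median of 2.10, and for 18 of 18 class I genes with a median of 1.44. Without the sparse back libraries and with the set term, back against tail is this same pair and no separate result. Leaving out the third back library raised the calls to 1972, and leaving out any other library gave between 3 and 111.

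Cell cycle genes were lower in back, with a positive difference in 3 of 26, a median of -1.46 and a camera adjusted p of 0.0064 (adjusted p = 0.50 with an estimated correlation). Bub1b alone fell over all genes (adjusted p = 0.037, or 0.071 with the set term), and 4 passed when adjusted over the list alone. In the third pair 14 of 26 were positive with a median of 0.06, and the list did not pass camera without the first and second back libraries. Mitochondrially encoded genes were positive in 13 of 13, with a median of 0.84 and a camera adjusted p of 6.3e-12 (adjusted p = 0.24 with an estimated correlation). In the third pair 10 of 13 were positive with a median of 0.25. The list did not pass camera without the first and second back libraries and with the set term, which compares that same pair. Only mt-Nd4 rose over all genes (adjusted p = 0.0495, or 0.081 with the set term) and 11 passed when adjusted over the list alone.

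Markers of other cells differed between back and tail. Krt77, a keratin of differentiated epidermal cells, was at 0 counts in all 3 tail libraries and at 8977 ± 7092 normalised counts in back (SD, n = 3), and it rose (adjusted p = 0.022). The differentiated keratinocyte list had a median difference of 1.05 and a camera adjusted p of 0.0028 (adjusted p = 0.50 with an estimated correlation), but in the third pair its median was -1.17 with 4 of 17 positive. The class II gene H2-Aa of antigen-presenting cells rose by 2.96 (adjusted p = 0.045, or 0.071 with the set term). The Langerhans and myeloid list passed camera (adjusted p = 0.013, 0.35 with an estimated correlation), with a median difference of 0.26. Its mean level was higher in each back library than in each tail library, by 0.76 on average (exact permutation p = 0.1, the smallest possible with 3 against 3). All 11 lists of other cells were compared this way in the 3 comparisons. Of these 33 tests 6 reached the smallest p, and the lowest adjusted p was 0.51.

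Ribosomal protein genes were higher in back in 70 of 86, with a median of 0.21 (camera adjusted p = 1.3e-07, 0.36 with an estimated correlation), and 0 passed over all genes or over the list alone. Nuclear oxidative phosphorylation genes had a median of 0.12 (camera adjusted p = 2.3e-05, 0.31 with an estimated correlation), Cox7c rose by 0.92 (adjusted p = 0.039, or 0.076 with the set term), and 7 passed when adjusted over the list alone. Anterior and central HOX genes, with Hoxb2, had 0.46 (camera adjusted p = 0.040, 0.29 with an estimated correlation) and 1 over the list alone. Hair follicle and sebaceous genes had 0.36 (camera adjusted p = 0.021, 0.31 with an estimated correlation), with Mgst1 the 1 member past the threshold over all genes and over the list alone (adjusted p = 0.038, or 0.060 with the set term). T cell genes had 0.27 (camera adjusted p = 0.022, 0.36 with an estimated correlation), with 0 over all genes and 0 over the list alone.

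Of the 14 lists past camera in back against tail, none passed with an estimated correlation, and apart from that and fry 4 passed in every other setting and every fit with 1 library left out: immediate early, class I, chemokine and ribosomal genes. Interferon, mitochondrially encoded, nuclear oxidative phosphorylation and cholesterol genes each passed in 15 of 16 other settings, nuclear oxidative phosphorylation genes failing with quantile normalisation (0.21). Cell cycle genes passed in 12 of 16, Langerhans genes in 12 of 16, T cell genes in 12 of 14, hair follicle genes in 11 of 15 and HOX genes in 9 of 14. Differentiated keratinocyte genes passed in 11 of 16 and in the opposite direction in 1. That setting leaves out the sparse back libraries and has the set term, so it is the third pair alone.

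In the third comparison, knockout back against control tail, genotype and body site differ together and cannot be separated. Interferon and class I genes were higher in back than in control tail. All 24 interferon list members had a positive difference, with a median of 2.22, and 7 rose. Oas1a differed by 4.77, Usp18 by 3.73 and Stat2 by 2.43, with adjusted p of 0.036, 0.039 and 0.045. Over the list alone 16 passed, and with the set term 15 passed over all genes. The camera adjusted p was 4.5e-19 (adjusted p = 0.19 with an estimated correlation). Of 18 class I genes 9 rose, with 13 when adjusted over the list alone and a median of 2.14 (camera adjusted p = 2.9e-17, 0.19 with an estimated correlation). H2-K1 differed by 3.10 (adjusted p = 0.028). Immediate early genes had a median of 1.06, and Fosb, Egr1 and Zfp36 rose (adjusted p of 0.039, 0.042 and 0.045; camera adjusted p = 6.2e-13, 0.19 with an estimated correlation), with 12 when adjusted over the list alone.

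Outside those lists Iigp1, the complement gene C4b, Ifitm3, Tgtp1 and Krt77 rose most, by 5.64, 4.81, 4.71, 4.50 and 4.29. Met, a receptor tyrosine kinase of the melanocyte lineage, rose by 1.54 (adjusted p = 0.046), Mlana by 0.97 (adjusted p = 0.036) and Bcl2 by 1.82 (adjusted p = 0.042). Prl2c5, Napsa and Ccnd1 fell, with differences of -7.90, -4.30 and -2.36 (adjusted p of 0.028, 0.036 and 0.036). Prl2c5 also had a lower mean in knockout tail than in control tail, 25265 against 159936 normalised counts, a difference that did not pass (for Prl2c5, adjusted p = 0.083 with the set term).

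Cell cycle genes were lower in back than in control tail, with a median of -1.37 (camera adjusted p = 0.032, 0.59 with an estimated correlation), and 0 passed over all genes or over the list alone. Melanin and melanosome genes passed camera with a median of 0.02 (adjusted p = 0.044, 0.35 with an estimated correlation), 2 over all genes and 8 over the list alone. Lineage regulators passed (adjusted p = 0.033, 0.25 with an estimated correlation) with a median of 0.15 and a mean of -0.04, which differ in sign, 1 over all genes and 5 over the list alone. Apoptosis and survival genes had 0.18 (camera adjusted p = 0.033, 0.31 with an estimated correlation), with Bcl2 the 1 member over all genes and over the list alone. Mitochondrially encoded genes had 0.36 (camera adjusted p = 1.0e-04, 0.35 with an estimated correlation) and nuclear oxidative phosphorylation genes 0.03 (camera adjusted p = 0.010, 0.45 with an estimated correlation), with 0 of either over all genes, and 0 and 1 over the list alone.

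Among lists of other cells, Langerhans and myeloid genes had a median of 0.71 (camera adjusted p = 0.0067, 0.32 with an estimated correlation), with 1 over all genes and 4 over the list alone. Hair follicle and sebaceous genes had 0.18 (camera adjusted p = 0.049, 0.35 with an estimated correlation), with 1 and 2. Muscle, fat and blood genes had 1.30 (camera adjusted p = 0.022, 0.35 with an estimated correlation), with 0 and 1.

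Of the 14 lists past camera in back against control tail, none passed with an estimated correlation, and apart from that and fry 4 passed in every other setting and every fit with 1 library left out: interferon, class I, immediate early and chemokine genes. Mitochondrially encoded genes passed in 13 of 16 other settings and cell cycle genes in 11 of 16. Without the sparse back libraries and with the set term, which leaves 1 back library, both lay in the opposite direction, short of the threshold. Melanin genes passed in 9 of 16, lying in the opposite direction with quantile normalisation (0.87). Lineage regulators passed in 9 of 16, nuclear oxidative phosphorylation genes in 10 of 16 and apoptosis genes in 7 of 16. Langerhans genes passed in 13 of 16, the blood list in 12 of 14 and hair follicle genes in 8 of 15, failing with the set term (0.057).

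The limma group-only fit called 163 genes, 63 higher and 100 lower, and 545 with the set term, 171 higher and 374 lower. All 163 were among the 545. Without the first and second back libraries the counts were 0 and 8. Leaving out the third back library gave 2804 calls, the third knockout tail library 87 and the second 11, the second back library 1, and any of the other 5 libraries 0. Median centring turned the split to 131 higher and 32 lower, and quantile normalisation gave 281 and 298.

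The comparisons against control tail share the same 3 control libraries. Their log2 differences correlated across genes with r = 0.40, where simulated unchanged groups gave 0.40 ± 0.01 (SD, 100 draws). Genes were drawn independently in the simulation, so this SD leaves out correlation between genes. The simulation therefore cannot show whether the covariances below exceed those of unchanged groups. The covariance was 0.147 against 0.117 in simulation. With the set term r was 0.55 against 0.53 and the covariance 0.258 against 0.193. No gene was called in both comparisons in the group-only fit, which follows from the 0 calls in knockout tail against control tail. With the set term 6 genes were higher and 3 lower in both, where independent lists would share 0.073 and 0.069. The 3 controls cannot be split into 2 sets of at least 2, so part of the excess may come from the shared controls.

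**Figure D3:**
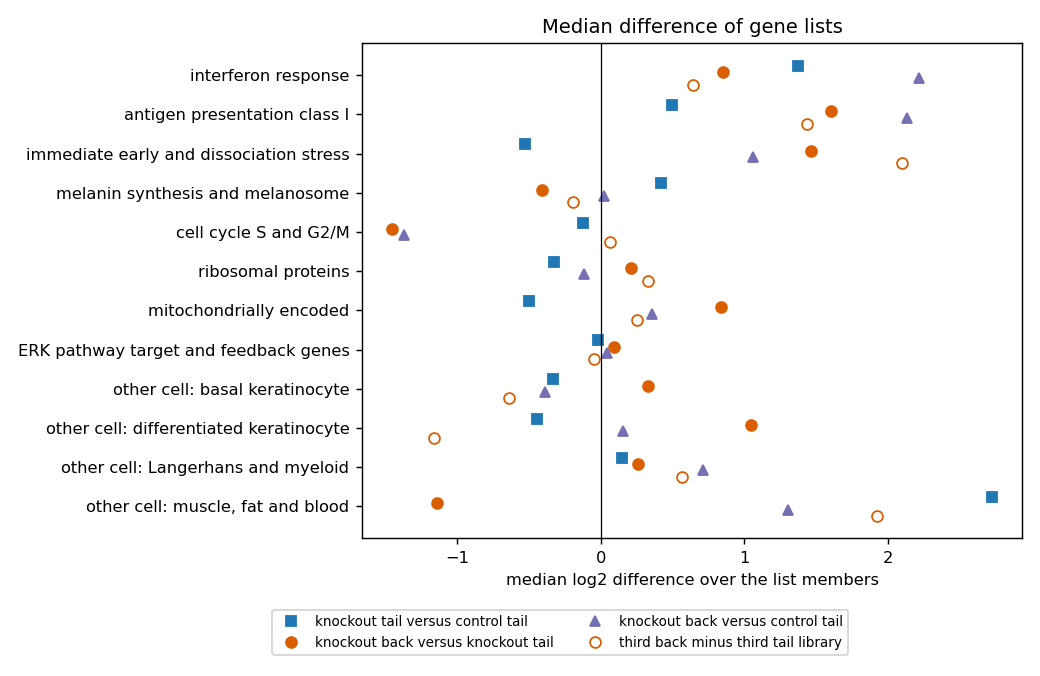
Median log2 difference over the members of 12 gene lists (x axis) in the 3 comparisons, with the third back library minus the third tail library as open circles. Interferon genes are at 1.37, 0.85 and 2.22, and immediate early genes at -0.53, 1.47 and 1.06, in the order of the comparisons.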

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

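Settings that use the library sets, the sparse libraries, array weights, a mean of at least 10 or genes with no library at 0 counts were chosen after seeing the data. Where a value changed, the cause was not tested unless fewer libraries or genes entered the fit. No called gene that is named changed sign in any setting run. Among planned settings 884 named-gene values kept sign and status, 601 lost a call, 8 gained one and 15 changed sign while uncalled. Among added settings these were 640, 267, 36 and 11. Values that kept their status include genes uncalled in both fits, so they do not count calls that held. The filters "no filter" and a mean of at least 5 removed no gene and are void. Another pseudocount was not run, since the values are already logarithms.

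Genes called in knockout tail against control tail, 0 in the main fit, were 10 with the library set as a term, 9 of them with a fold of at least 2, 6 with the shift undone, 130 with array weights and the set term, and 6 among genes with no library at 0 counts and the set term. Leaving out 1 library gave 0 to 0. Genes in both comparisons against control were 0 in the main fit. They were 9 with the set term, 6 with the shift undone and 20 with array weights and the set term. With the set term and no library at 0 counts they were 6.

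Knockout back against knockout tail had 244 calls in the main fit. It gave 76 with median centring and 2 with only the groups compared. The set term gave 71, 67 of these with a fold of at least 2. The 7 libraries of the larger set gave 1637, and the shift undone 31. Array weights gave 1325, or 6 with the set term. Without that term the third back library had a weight of 5.06, against 0.24 and 0.16 for the first and second. The 1325 calls thus rest mostly on 1 back library. With the term its weight was 0.69. A mean of at least 10 gave 84. Genes with no library at 0 counts, fitted with the set term, gave 30, against 71 with the set term alone. Leaving out 1 library gave 3 to 1972.

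Knockout back against control tail had 163 calls in the main fit. It gave 579 with quantile normalisation, 471 without trend or robust moderation and 7 with only the groups compared. Limma-voom gave 317, or 428 with the set term. The set term gave 545, 498 of these with a fold of at least 2. The 7 libraries gave 2371, and the shift undone 217. Array weights gave 903, again resting mostly on the third back library, or 37 with the set term. A mean of at least 10 gave 284. Genes with no library at 0 counts, fitted with the set term, gave 298, against 545 with the set term alone. Leaving out 1 library gave 0 to 2804.

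Lists past the camera threshold were 14 in each comparison. In knockout tail against control tail this was 9 with limma-voom, 0 with an estimated correlation, 0 with that and the set term, and 1 with fry, and 10 to 15 when 1 library was left out. A mean of at least 10 left 24 of the 32 lists to test, and no library at 0 counts with the set term left 25. In back against knockout tail these settings gave 9 and 9. There it was 0 and 0 with an estimated correlation, 2 with fry, and 9 to 15 with 1 library left out. In back against control tail it was 8 with quantile normalisation. It was 6 of 24 lists at a mean of at least 10 and 5 of 25 with no library at 0 counts and the set term. With an estimated correlation it was 0 and 0, with fry 3, and with 1 library left out 8 to 15.

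Whether the replicate numbers pair the samples could not be told for the third tail and back libraries, which form the smaller set. Their correlation of deviations was -0.70 in the deposited values, where the shift removal sets them against each other. With the shift undone it was 0.33, where a shared set cannot be told from pairing. Other same-numbered pairs lay between -0.17 and 0.14. With a replicate block the calls were 0, 21 and 42 in the 3 comparisons, 11 higher and 10 lower, then 27 higher and 15 lower.

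Spry1 in back against tail was 0.22 without the sparse libraries and with the set term; against control it was 0.0289 and 1.005 without the sparse libraries, without and with the set term, and -1.38 to 0.34 with 1 library left out. With 1 library left out Spry1 ranged from 0.08 to 0.79 in knockout tail against control tail and from -1.85 to -0.12 in back against tail. With the median over list members taken in each library in place of the mean, the level of the basal keratinocyte list differed by 0.38 in back against control (-0.53 with the mean) and that of the Langerhans and myeloid list by 0.28 in knockout tail against control (0.11 with the mean).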

Other observations

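Lists of chemokine and cytokine genes and of cholesterol synthesis genes passed camera without a member past the threshold over all genes. Of 21 chemokine and cytokine genes 15 had a positive difference in knockout back against knockout tail, with a camera adjusted p of 0.0024 (adjusted p = 0.19 with an estimated correlation). In back against control tail 16 of 21 were positive, with a camera adjusted p of 0.0011 (0.19 with an estimated correlation). Cholesterol synthesis genes had a median difference of 0.34 in back against tail (camera adjusted p = 3.8e-05, 0.19 with an estimated correlation) and -0.31 in knockout tail against control tail (camera adjusted p = 0.022, 0.31 with an estimated correlation, and 0.084 with the set term). Over the list alone 2 and 1 chemokine genes and 3 and 0 cholesterol genes did. In back against control tail cholesterol genes had 0.05 (camera adjusted p = 0.022, 0.31 with an estimated correlation), with 3 over the list alone. In the third back against the third tail library 14 of 21 cholesterol genes were positive with a median of 0.22. Without the sparse back libraries and with the set term, which compares that same pair, the list did not pass in back against tail. In back against control, with 1 back library left, it passed neither without nor with the set term, and with it the direction was reversed. In back against control tail cholesterol genes passed in 9 of 16 other settings, and in knockout tail against control tail in 13 of 16. Adhesion and migration genes were higher in 19 of 24 in knockout tail against control tail (camera adjusted p = 1.7e-04, 0.19 with an estimated correlation), with 1 when adjusted over the list alone.

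All tests below were chosen after the results they bear on had been seen. Only the bounds for the repeat of lower genes in the third pair of libraries were written before that outcome was known. For thinning and for immediate early genes in the third pair, values that imply the outcome had already been seen when the bounds were written.

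Interferon response genes were higher in knockout tail than in control tail. The removed shift between library sets is argued against as the whole cause: within the 7 libraries of the larger set, which the shift moves together, 24 of 24 members were positive with a median of 1.70. RNA from Langerhans, other myeloid or T cells could not be excluded. Their 19 markers had a median difference of 0.065 against 1.37 for the interferon list. That median cannot decide, since deposited values understate changes of genes with few counts and had the set shift removed. The T cell list mean was 8.23 to 8.67 in knockout tail, near the 7.98 of 0 counts. Cd74, a very abundant transcript of antigen-presenting cells, had 132, 8 and 4443 counts in the knockout tail libraries. In control tail it had 5, 162 and 3. H2-Aa had 0, 0 and 1108 against 0, 6 and 0. In the first and second knockout tail libraries neither lay above all controls. Lyz2 did, with 1125 and 568 against 461, 110 and 146. Sex of the animals could not be separated from genotype: the third knockout tail library, which has no Ddx3y counts, as the controls, lay above them by a median of 1.98 in 19 of 24 members with the set shift taken from the back libraries (2.28 in 23 of 24 without), but it is 1 library. An effect of keratinocyte Spry1 loss on melanocytes and a response carried by keratinocyte RNA within the sort both stay open and were not tested. Single-cell profiles of the same sort would tell them apart, by whether cells with melanocyte transcripts carry the interferon genes.

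More genes were lower than higher in knockout back against knockout tail. Depth is argued against: with each library thinned to 45.7 M counts, the sparse back libraries still had at least 2.64 times as many genes at 0 as the highest of the other 7 (4638 against 1755). The sparse libraries themselves are a candidate explanation. Of 1301 genes called lower from the 7 libraries of the larger set, 57.6% were lower in the third back library than in the third tail library, against 49.7% of all genes. Their median difference there was -0.13 against -2.08 in the 7 libraries. For the 336 genes called higher the repeat was 59.2%. A true site difference in some of these genes stays open.

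Immediate early genes were higher in knockout back. The sparse libraries stay open as a cause, since only 1 back library lies outside them. In that library 20 of 20 members were higher than in the third tail library, with a mean difference of 2.00, where the spread between replicates of the larger set would allow 0.68 for 1 library against 1. Time or handling during tissue dissociation, which is known to raise these genes, cannot be told apart from body site: 20 of 20 members follow the tissue that was dissociated, and the labels give no handling time. A difference between back and tail melanocytes in the animal stays open and was not tested. Tissue fixed before dissociation would separate it from handling.

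Each comparison has 10 splits of its 6 libraries, too few for a share under 0.05. Knockout back against knockout tail called 244 genes in the real split, the 1 split of 10 with as many, and the highest of the other splits called 0. Knockout back against control tail called 163, again the 1 split of 10, with 0 as the highest other. Knockout tail against control tail called 0 in all 10 splits. At an unadjusted p under 0.05 the real splits had 3474, 4255 and 814 genes, and the highest other splits 2389, 1130 and 487.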
